A study of Glycine max with 46 samples.

How the data were processed

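Total RNA from soybean seeds at 7 stages was sequenced as Illumina cDNA libraries. Per the labels' protocols, embryos were collected, RNA was extracted with a Qiagen column kit that included a DNase digestion on the column, libraries were made with the Illumina TruSeq RNA kit, and plants grew under 16 h light and 8 h dark at 22 °C. Labels number 3 biological replicates per stage and 2 or 3 sequencing runs per replicate. Per the submitters' processing notes, Trimmomatic 0.38 and HISAT2 were used. The counting tool, genome build, annotation and HISAT2 version are not given in the sources used here, nor is whether counting used strand, so overlapping and antisense genes cannot be told apart, and genes with near-identical copies are uncertain.

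The deposited table holds 1 signal value per gene and library, which the authors made by dividing read counts by a size factor per library (DESeq-normalized counts per the name they gave the table). In each library all values were whole multiples of the value of 1 read within a tolerance of 0.001 reads (100% of values), so whole reads were recovered. This gave 2.47 to 80.08 M reads per library, with 1 read worth 0.173 to 8.95 normalized counts. The table lists 54175 genes and no summary rows. Of the 46 samples in the labels, 45 matched a column. 1 column of the table matched no sample label and was not used in any step, so late desiccation replicate 3 rests on its first run, 2.53 M reads; whether that column holds a further run of this replicate is left open. The precision of low values is set by this depth. In that replicate 1 read is worth 8.68 normalized counts, and floors given in the text, 3 reads over the replicates of a stage, cover counting error only.

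Runs of a replicate were averaged, giving 21 biological replicates. The deposited scaling was kept. Genes with at least 10 normalized counts in at least 3 replicates were tested (46537). Tests used limma 3.58.1 in R 4.3.3 on log2(value + 1), with 1 mean per stage, a variance trend and robust moderation, all 7 stages in 1 fit, and Benjamini-Hochberg adjustment within each of 8 comparisons. A gene was called at an adjusted p under 0.05 and a change of at least 2-fold on this scale, which understates changes of low genes. Adjusted p-values in the text come from limma unless another tool is named, and ± gives SD for levels and SE for log2 changes. The procedure was tested on simulated counts for 27 h against dry seed over 40868 genes with 200 changed genes. Of these, 91% of the 4-fold and 96% of the 8-fold changes were recovered, with 5 false calls. The changed genes were drawn only from genes of middle level in dry seed. Recovery of changes in low genes was therefore not measured. Every stage was drawn from dry seed means with independent noise, without a background that differs between replicates of a stage. The 5 false calls do not cover errors from such a background. Shares of the most abundant genes were compared before and after imbibition with an exact permutation test over all arrangements of the 7 stage means, two-sided. Composition, overlaps and figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Overlaps between comparisons are set beside the product of both list sizes divided by the genes tested.

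Genes named in the text follow a rule set before the data were examined: called genes whose replicates do not overlap between the stages and whose higher stage mean is at least 100 normalized counts, taken from the largest change down. The rule also asked for an informative product, and 33 gene lists and 7 regulators were set beforehand. None of these could be applied. None of the 54175 IDs matched the table of 59048 genes for assembly Glycine_max_v4.0, which gives no products (0 matched), and 0 of the 7 regulator IDs were found, so gene list tests were not run and names are not given. At most 2 rising and 2 falling IDs are printed per comparison.

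Alternatives set before the data were examined were a pseudocount of 5, no filter, TMM scaling, run 1 alone, the replicate number as a block, no fold threshold, fits of the compared stages alone, edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on recovered reads, and leaving out each replicate. The edgeR test on recovered reads called 13984 genes for 27 h against dry seed and DESeq2 16088. Added after seeing the data were a limit to genes for which the mean of both compared stages is at least 200, a limit to genes with a mean of at least 200, the lower quartile of each library as a covariate, and leaving out both early desiccation replicate 3 and late desiccation replicate 3, without and with dry seed replicate 1. TMM moved the median log2 change of all genes relative to the deposited scaling by 0.24 for mid against early desiccation, -0.27 for late against mid desiccation, 0.32 for dry seed against late desiccation and 0.28 for dry seed against early desiccation.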

Results

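RNA-seq was used to follow gene activity in soybean (Glycine max, cultivar Williams 82) seeds from the drying phase of maturation to the first day after water uptake. The labels name the tissue as whole seed, while the protocol speaks of embryos. Samples fall into 7 stages with 3 biological replicates each: early, mid and late desiccation, dry seed, and 3, 16 and 27 h after imbibition, which is the uptake of water that starts germination. By the labels each replicate was sequenced in 2 or 3 runs, 46 in all, of which 45 had values and are used here. Recovered depth per replicate, in mega-reads (M), ranged from 2.53 M reads in late desiccation replicate 3, represented here by 1 of its runs, to 86.52 M in 16 h replicate 1. The other replicates held at least 43.82 M. Values are normalized counts, and 1 read was worth between 0.173 and 8.95 of them depending on the library. Genes are named by the IDs of the table only, since the files do not pair these IDs with names, and at most 2 IDs that rose and 2 that fell are given for each comparison.

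The share of the libraries taken by the most abundant transcripts was lower at 16 h and 27 h after water uptake, while at 3 h it lay above dry seed. The 100 most abundant genes of each library held 30.7% ± 3.08 of the normalized total in early desiccation (mean ± SD, n = 3), 26.9% ± 1.25 in dry seed, 29.3% ± 2.76 at 3 h, 21.3% ± 1.45 at 16 h and 14.1% ± 0.165 at 27 h. The genes themselves were replaced as well: of the 100 genes with the highest means at a stage, 71 were shared between late desiccation and dry seed, 77 between dry seed and 3 h, 79 between 3 h and 16 h, and 44 between 16 h and 27 h. The 100 leading genes of early desiccation held 30.4% ± 3.45 of the total at that stage and 6.33% ± 0.550 at 27 h (n = 3). Over all replicates, the share of the 100 most abundant genes was 30.3% ± 2.97 in the 12 replicates before imbibition and 21.6% ± 6.79 in the 9 after it. With stages as the units, the difference did not pass 0.05 (exact permutation test on stage means, 4 against 3, 35 arrangements, two-sided p = 0.0571, adjusted p = 0.0857 over 3 measures, smallest p possible 0.0286). The share of the 10 most abundant genes was 11.7% ± 1.81 before and 8.70% ± 3.73 after (exact p = 0.229, adjusted p = 0.229). The total of normalized counts was 19.2 M ± 2.04 before and 14.6 M ± 3.21 after (exact p = 0.0571, adjusted p = 0.0857). No single pair of stages was tested this way, because 3 against 3 replicates cannot give an exact two-sided p below 0.1.

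**Figure D1:**
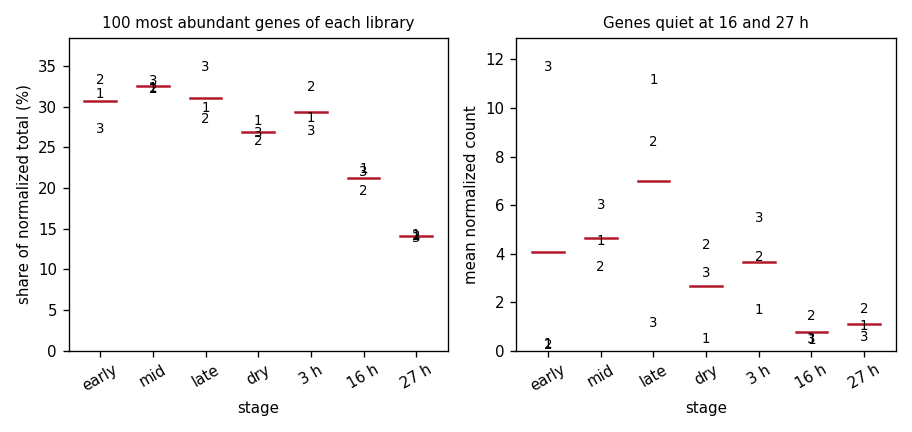
Left, share of the normalized total (%) held by the 100 most abundant genes of each replicate, by stage. Right, mean normalized count of the 8959 genes whose mean lies below 2 at 16 and 27 h. Numbers are replicates and red lines are stage means (n = 3). The share lies at 14.1% at 27 h against 30.7% in early desiccation. The quiet genes lie at 11.7 in early desiccation replicate 3 and at 0.252 and 0.233 in replicates 1 and 2.

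Across the 7 stages, 17459 of 46537 genes tested changed (limma F test, adjusted p under 0.05, range of stage means at least 2-fold). Of these genes, 7202 (41.3%) had their highest mean at 27 h, 3120 (17.9%) in dry seed, 1804 (10.3%) in early desiccation, 1705 (9.8%) in mid desiccation, 1613 (9.2%) at 3 h, 1137 (6.5%) at 16 h and 878 (5.0%) in late desiccation. The order depended on abundance: of the 12218 genes whose highest stage mean was at least 200, 37.1% peaked at 27 h and 21.3% in dry seed, while of the 8394 with a mean of at least 200 over all stages 23.5% peaked at 27 h and 27.3% in dry seed. Profiles of stage means over the 11967 genes with a mean of at least 200 correlated at r = 0.970 between early and mid desiccation, 0.893 between late desiccation and dry seed, 0.919 between dry seed and 3 h, 0.817 between 3 h and 16 h, 0.601 between 16 h and 27 h and 0.219 between dry seed and 27 h. These correlations are across genes, which are not independent replicates. Quiet genes differed between replicates of a stage. In early desiccation replicate 3 the 8959 genes with a mean below 2 at 16 and 27 h had a mean of 11.7 normalized counts, against 0.252 and 0.233 in replicates 1 and 2. In late desiccation they lay at 11.2, 8.61 and 1.14 in replicates 1, 2 and 3, and in dry seed at 0.475, 4.37 and 3.19. Early desiccation replicate 3 and late desiccation replicate 3 stood apart from the other replicates of their stages, but not to the same degree. In early desiccation replicate 3, 15.4% of very abundant genes lay at least 2-fold off its stage after the median difference was removed. In late desiccation replicate 3 this was 3.7%, less than the 7.4% of 27 h replicate 1, though its correlation with its stage was 0.798. Dry seed replicate 1 stood apart in quiet genes, with 20482 genes at 0 reads against 4649 and 4577 in replicates 2 and 3, while over very abundant genes it correlated at 0.974 with them. Without the first pair 38000 genes changed across the stages, and 40072 without all 3 libraries. Leaving out the pair widens the gap in quiet genes, since early desiccation then holds only the replicates at 0.252 and 0.233 and late desiccation those at 11.2 and 8.61.

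**Figure D2:**
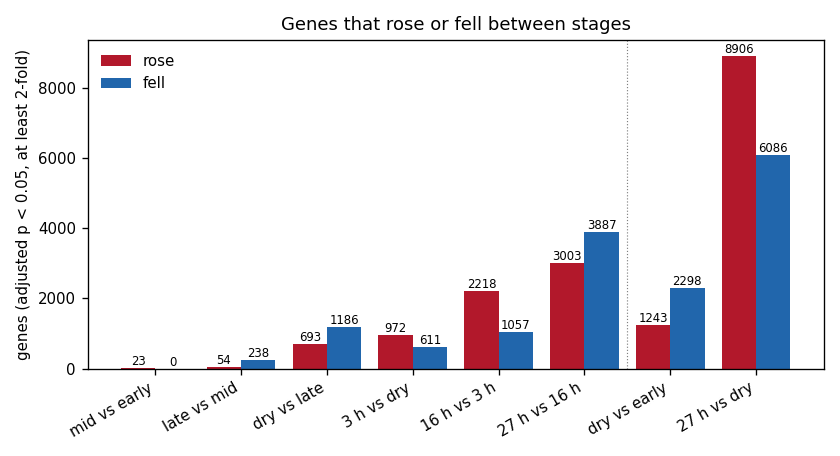
Genes that rose (red) or fell (blue) in each comparison by limma at adjusted p under 0.05 and at least 2-fold, out of 46537 tested. The dotted line parts the 6 consecutive comparisons from the 2 that span several stages. Counts go from 23 between early and mid desiccation to 6890 between 16 h and 27 h, and to 14992 between dry seed and 27 h.

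The first comparison asks what changed between early and mid desiccation. With all libraries a small set of genes rose and none fell. Glyma13g37770 went from 2.97 ± 5.15 to 357 ± 62.9 normalized counts (mean ± SD, n = 3; log2 change 7.37 ± 0.85 SE, limma adjusted p = 0.00113). Glyma12g32690 went from 10 ± 6.77 to 1010 ± 343 (log2 change 6.64 ± 0.92 SE, limma adjusted p = 0.00992). In late desiccation these genes stood at 25.9 ± 21.9 and 215 ± 219, and their highest stage means were at 27 h, with 4640 ± 701 and 5640 ± 852. In all, 23 genes rose and 0 fell by limma, with 2157 genes at an unadjusted p under 0.05. For falls, DESeq2 gave 1 gene and edgeR 0. The count rested on single libraries: it was 9223 without early desiccation replicate 3, 7, 9, 3 and 8 without early desiccation replicates 1 and 2 and mid desiccation replicates 1 and 2, and 18014 without the pair that stood apart. Of these, 281 of the 9223 and 338 of the 18014 were falls. In both fits early desiccation kept only replicates 1 and 2, with quiet-gene means of 0.25 and 0.23. In mid desiccation these means were 4.54, 3.46 and 5.98. How many of the rises come from this gap was not tested. The call of Glyma12g32690 was lost without early desiccation replicate 1 or 2 or mid desiccation replicate 1 or 2.

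Between mid and late desiccation, falls outnumbered rises. Among the genes that rose, Glyma19g26850 went from 579 ± 169 to 10700 ± 8020 normalized counts (n = 3; log2 change 4 ± 0.73 SE, limma adjusted p = 0.0150) and Glyma19g37108 from 1250 ± 638 to 19800 ± 15800 (log2 change 3.89 ± 0.59 SE, limma adjusted p = 0.00934). Among those that fell, Glyma13g37770 decreased to 25.9 ± 21.9 (log2 change -4.04 ± 0.85 SE, limma adjusted p = 0.0286), and Glyma06g45430 went from 448 ± 159 to 49.8 ± 38.3 (log2 change -3.52 ± 0.56 SE, limma adjusted p = 0.00889). By limma, 54 genes rose and 238 fell, so that 18.5% of the 292 calls were rises; with TMM scaling this share was 1.2% of 992 calls, with edgeR 1.1% of 1005 and with DESeq2 13.8% of 607. Fitting these 2 stages alone gave 0 genes by limma, with 3321 at an unadjusted p under 0.05. Fitted on all 7 stages, DESeq2 and edgeR gave 607 and 1005; neither was run on these 2 stages alone. The count was 833 without late desiccation replicate 3, 82 and 15 without late desiccation replicates 1 and 2, 168 and 11 without mid desiccation replicates 1 and 2, and 1190 without the pair that stood apart. Glyma13g37770 was no longer called without any 1 of the mid desiccation replicates or without late desiccation replicate 2, Glyma19g26850 without mid or late desiccation replicate 2 and with run 1 alone (adjusted p = 0.0531), and Glyma06g45430 without mid desiccation replicate 2. For Glyma19g26850 and Glyma19g37108 DESeq2 gave log2 changes of 5.89 and 4.65 with no adjusted p.

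From late desiccation to dry seed, a pair of very abundant transcripts fell to low levels. Glyma11g33922 went from 173000 ± 136000 to 6.40 ± 6.21 normalized counts (n = 3; log2 change -14.89 ± 1.56 SE, limma adjusted p = 5.85e-05) and Glyma09g28800 from 357000 ± 264000 to 32.0 ± 23.9 (log2 change -13.67 ± 1.51 SE, limma adjusted p = 8.69e-05). These genes varied 3.93-fold and 3.95-fold between the replicates of late desiccation, and DESeq2 gave log2 changes of -13.84 and -12.66 with no adjusted p. Glyma06g44380 went up from 79.8 ± 70.4 to 2180 ± 643 (log2 change 6.45 ± 1.45 SE, limma adjusted p = 0.0114) and Glyma05g27415 from 12.6 ± 13.6 to 254 ± 42.0 (log2 change 5.19 ± 1.33 SE, limma adjusted p = 0.0163). Fitting these 2 stages alone lost the call of Glyma06g44380 (adjusted p = 0.326), and its log2 change was 4.15 without late desiccation replicate 3 and 4.07 with edgeR. Glyma05g27415 had means of 20.9 or lower at the other 6 stages, but its call here was lost without late desiccation replicate 3 or dry seed replicate 1, and with edgeR. Of 1879 genes called by limma, 693 rose and 1186 fell, and 10 genes went from at least 100 normalized counts in all 3 replicates to below 10 in all 3. Of the falls, 13 belonged to a run of 14 genes on chromosome 13 with 0 reads in dry seed, which follow each other in ID order when only genes with a mean of at least 10 in the other stages are kept. Their falls may not reflect transcript levels, and genes of this run were not taken out of the counts above. The balance of rises and falls depended on the processing, with 36.9% of calls rising here, 33.2% of 2813 with DESeq2, 62.9% of 4114 without a fold threshold, 81% of 3116 with TMM scaling and 88.4% of 3182 with edgeR. Among 11101 genes for which the mean of both stages was at least 200, 56.2% of 808 calls were rises. The count was 1231 without dry seed replicate 1, and without the pair that stood apart 10169 genes changed, of which 10.2% rose; without dry seed replicate 1 as well it was 4805, with 18.3% rising.

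Over the whole of desiccation, from the early stage to dry seed, Glyma05g27415 went from 9.15 ± 15.8 to 254 ± 42.0 normalized counts (n = 3; log2 change 6.37 ± 1.33 SE, limma adjusted p = 0.00205). Glyma12g32690 went from 10 ± 6.77 to 638 ± 450 (log2 change 5.79 ± 0.92 SE, limma adjusted p = 0.000447). Glyma13g04690 and Glyma13g01891 went from 805 ± 208 and 614 ± 352 to 0 reads in dry seed. Taking 3 reads over the 3 dry seed replicates as the floor, they were at least 2150-fold and 1640-fold lower, counting error only. Both lie in the run of 14 genes with 0 reads in dry seed, so these falls may not reflect transcript levels. In all 1243 genes rose and 2298 fell by limma, 67 and 139 of them by 8-fold or more. With TMM scaling the share of rises was 70.6% of 4057 calls, with edgeR 71.7% of 4155 and with DESeq2 32.9% of 4381, against 35.1% here. Without early desiccation replicate 3 the count was 7407, and without the pair that stood apart it was 12585, with 72.8% rising. Without dry seed replicate 1 as well it was 21922, with 84% rising.

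**Figure D3:**
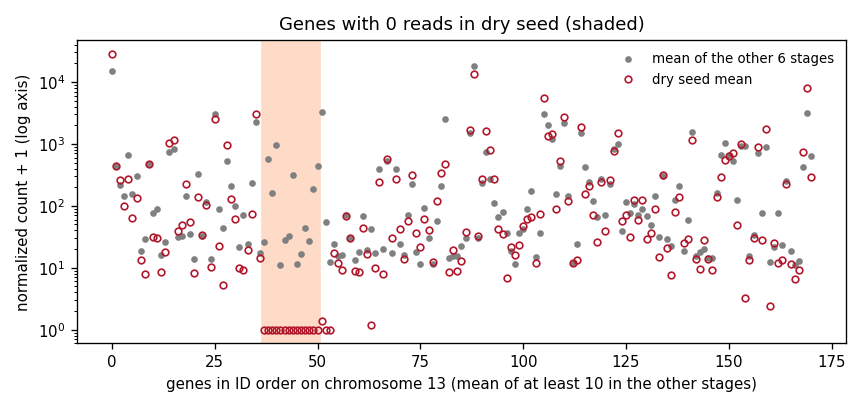
Normalized counts plus 1 (log axis) of genes on chromosome 13 in the order of their IDs, for genes with a mean of at least 10 over the other 6 stages. Red circles are dry seed means and grey points the means of the other 6 stages (n = 3 per stage). The shaded run of 14 genes has 0 reads in the 3 dry seed replicates.

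The comparison of 3 h with dry seed asks which genes changed first on water uptake. The largest rises were in genes with 0 reads in all 3 dry seed replicates: Glyma13g04690 reached 634 ± 82.7 and Glyma13g01891 337 ± 147 normalized counts (n = 3), at least 1690-fold and 899-fold above the floor of 3 reads over the dry seed replicates. Both belong to a run of 14 genes, Glyma13g01870 to Glyma13g12170, on chromosome 13 by the numbering of the IDs, singled out after its values were seen. These genes follow each other in ID order among genes with a mean of at least 10 in the other stages, and many IDs with lower means lie between them. Within this run 0 reads were found in dry seed, against at least 3979 in each other stage, and 14 of its genes were called at 3 h. This stretch may be missing from the mapping, the counting or the genome of that seed lot, so these rises may not reflect transcript levels. Glyma05g27415 went from 254 ± 42.0 to 7.90 ± 7.92 (log2 change -5.18 ± 1.33 SE, limma adjusted p = 0.0203) and Glyma16g10851 from 1260 ± 244 to 37.4 ± 15.6 (log2 change -5.10 ± 0.69 SE, limma adjusted p = 0.000187). In all 972 genes rose and 611 fell by limma, 96 and 18 of them by 8-fold or more. The share of rises was 61.4% here, 49% of 3096 without a fold threshold, 52.7% of 1771 with these 2 stages alone, 56% of 2046 with DESeq2 and 68.9% of 1411 with TMM scaling. The count was 1018 without 3 h replicate 2 and 2854 without the pair of other stages that stood apart (2896 without dry seed replicate 1 as well). The call of Glyma05g27415 was lost with edgeR and without any 1 of the dry seed replicates or 3 h replicate 1 or 2.

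Between 3 h and 16 h, genes that were almost silent before came up. Glyma07g37240 went from 1.38 ± 1.31 to 2090 ± 747 normalized counts (n = 3; log2 change 9.86 ± 0.87 SE, limma adjusted p = 2.86e-07) and Glyma01g04350 from 3.05 ± 1.71 to 2220 ± 426 (log2 change 9.17 ± 1.05 SE, limma adjusted p = 8.15e-06). Glyma04g39760 went down from 1380 ± 821 to 178 ± 7.97 (log2 change -2.78 ± 0.62 SE, limma adjusted p = 0.00551) and Glyma02g34780 from 153 ± 56.7 to 22.1 ± 6.11 (log2 change -2.71 ± 0.53 SE, limma adjusted p = 0.00144). Of 3275 genes called by limma, 2218 rose and 1057 fell. Rises of 8-fold or more numbered 464 and such falls 6, and 32 genes went from below 10 normalized counts in all 3 replicates to at least 100 in all 3. Without the pair of other stages that stood apart the count was 7014, with 51.1% rising against 67.7% here, and without dry seed replicate 1 as well 12236, with 36.5% rising. Among 11509 genes for which the mean of both stages was at least 200, 749 rose and 754 fell, and fitting these 2 stages alone gave 46.3% rising of 8813.

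The step from 16 h to 27 h gave the highest count of the 6 consecutive steps when all libraries were used, though not without the pair that stood apart, where early to mid desiccation gave 18014. That count is not a like measure, since early and mid desiccation then differ widely in quiet genes. Glyma09g03300 went from 5.41 ± 3.61 to 657 ± 121 normalized counts (n = 3; log2 change 6.85 ± 1.33 SE, limma adjusted p = 0.000483) and Glyma14g37440 from 48.1 ± 48.5 to 2330 ± 842 (log2 change 6.17 ± 1.68 SE, limma adjusted p = 0.0111); the latter call was lost without 16 h replicate 3. Glyma09g28800 and Glyma11g33922, which had fallen to 32.0 and 6.40 in dry seed, stood at 36700 ± 14300 and 24400 ± 8120 at 16 h and fell to 111 ± 140 and 64.3 ± 60.2 (log2 changes -9.33 ± 1.51 and -9.16 ± 1.56 SE, limma adjusted p = 0.00027 and 0.000428). DESeq2 gave log2 changes of -7.07 and -7.45 for them with no adjusted p. By limma 3003 genes rose and 3887 fell, and 10 genes were switched on and 23 off between below 10 and at least 100 normalized counts in all replicates. Among 12728 genes for which the mean of both stages was at least 200, 1580 rose and 2341 fell, so that 40.3% of calls were rises against 43.6% here; fitting these 2 stages alone gave 66.6% of 13457. Without the pair of other stages that stood apart the count was 10518, with 58.5% rising, and without dry seed replicate 1 as well 13734, with 66.3% rising.

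From dry seed to 27 h, 32.2% of the genes tested changed. Glyma02g03280 went from 15.5 ± 1.67 to 45500 ± 6050 normalized counts (n = 3; log2 change 11.42 ± 0.94 SE, limma adjusted p = 1.9e-08), after 6400 ± 766 at 16 h. Glyma17g02260 went from 5 ± 4.64 to 11700 ± 4410 (log2 change 11.40 ± 1.29 SE, limma adjusted p = 4.29e-07). Glyma10g32000 went from 6420 ± 763 to 6.91 ± 2.11 (log2 change -9.69 ± 0.61 SE, limma adjusted p = 3.82e-10), with 407 ± 131 already at 3 h. Glyma06g03110 went from 22000 ± 4390 to 29.0 ± 14.4 (log2 change -9.60 ± 0.33 SE, limma adjusted p = 1.05e-14), with 4520 ± 538 at 16 h. In all 8906 genes rose and 6086 fell by limma, and 3494 and 1317 of them changed by 8-fold or more. By the same limits on all replicates as above, 170 genes were switched on and 47 off. Of the rises, 11 belonged to the run of 14 genes with 0 reads in dry seed, and these may not reflect transcript levels. Among 12721 genes for which the mean of both stages was at least 200, 2889 rose and 3980 fell, 42.1% rising against 59.4% over all genes. The share of rises was 61.5% of 18781 calls without the pair of other stages that stood apart and 48.6% of 21292 without dry seed replicate 1 as well.

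**Figure D4:**
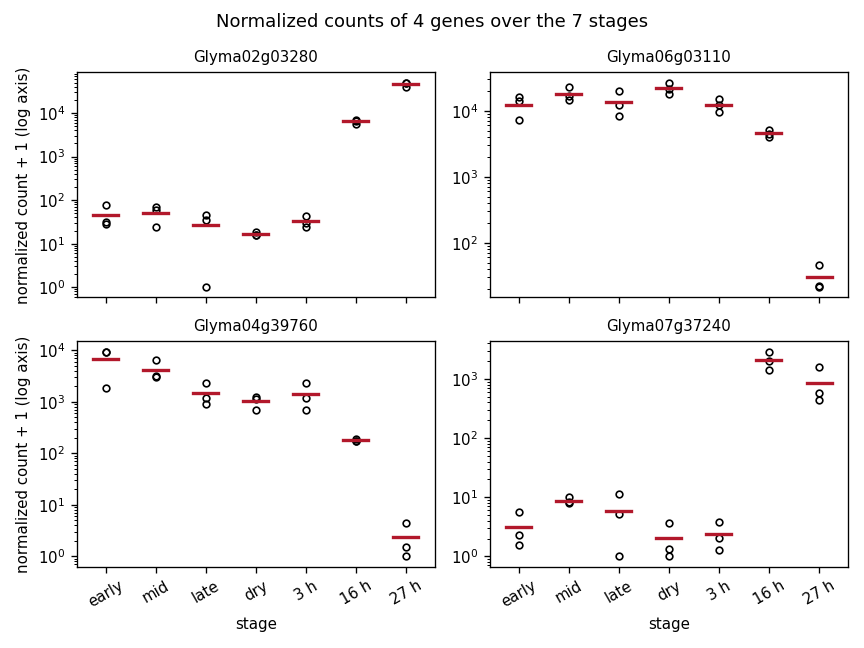
Normalized counts plus 1 (log axis) of 4 genes at the 7 stages. Circles are replicates and red lines stage means (n = 3). Glyma02g03280 rises from 15.5 in dry seed to 45500 at 27 h and Glyma06g03110 falls from 22000 to 29.0. Glyma07g37240 has a mean of 1.38 at 3 h and 2090 at 16 h, and Glyma04g39760 goes from 1380 to 178 in the same step.

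A last comparison asked whether genes that changed during desiccation moved back after imbibition. Changes from early to late desiccation and from dry seed to 27 h, which share no library, were nearly unrelated over 46537 genes (r = 0.0254 and Spearman rho = -0.00822, across genes, which are not independent replicates). Choosing 1 library per stage gave values from -0.482 to 0.510 over 81 choices. Among the genes with a mean of at least 200, r was 0.0278 and Spearman rho -0.121. Some lists of called genes overlapped more than independent lists would. The lists share each gene's estimate of spread, which by itself can raise such overlaps. Expected values divide by all genes tested, including low genes, which were called less often, and this can lower them. Of the 165 genes that rose from early to late desiccation by limma, 85 fell from dry seed to 27 h, against 21.6 expected for independent lists, and 8 rose, against 31.6 expected. Of the 125 genes that fell in desiccation, 34 rose by 27 h, against 23.9 expected, and 42 fell further, against 16.3 expected. Among the 11967 genes with a mean of at least 200 the excess was smaller: of 105 that rose, 63 fell, against 37.1 expected, and 6 rose, against 16.2; of 90 that fell, 21 rose, against 13.9, and 37 fell further, against 31.8. Without the pair that stood apart, 22175 genes rose in desiccation, of which 1232 fell by 27 h, against 3442.3 expected. That list is no test of the reversals, since the stages then differ in quiet genes by the gap given above.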

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

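The limits to genes with a mean of at least 200 over all stages or over both compared stages, the background covariate and the fits without both early and late desiccation replicate 3, with or without dry seed replicate 1, were chosen after seeing the data. In order, counts below are for mid against early desiccation, late against mid, dry seed against late, 3 h against dry seed, 16 h against 3 h, 27 h against 16 h, dry seed against early desiccation, 27 h against dry seed and all 7 stages, and only those over 1.5 times from 23, 292, 1879, 1583, 3275, 6890, 3541, 14992 and 17459 are given. TMM scaling gave 73, 992 and 3116 for the first 3, edgeR 77, 1005 and 3182, and DESeq2 70 and 607 for the first 2. Without a fold threshold, which adds genes by construction, late against mid gave 450, dry against late 4114, 3 h against dry 3096, 16 h against 3 h 5802 and dry against early 6488. With only the compared stages in the fit, late against mid gave 0 (3321 at an unadjusted p under 0.05; edgeR and DESeq2, fitted on all stages only, gave the 1005 and 607 above), dry against late 1084, 16 h against 3 h 8813 and 27 h against 16 h 13457. Genes with a mean of at least 200, fewer by construction, gave 909, 930, 1652, 3730, 1900, 6099 and 8449 from dry against late onward. A mean of both compared stages of at least 200, also fewer by construction, gave 12, 808, 778, 1503, 3921, 1803 and 6869, without late against mid. The background covariate gave 130, 751, 4589, 2728, 8100, 6451 (dry against early) and 26670 (all stages). Without both doubted libraries the values were 18014, 1190, 10169, 2854, 7014, 10518, 12585 and, for all stages, 38000; 27 h against dry seed gave 18781. Leaving out dry seed replicate 1 as well gave 20502, 1562, 4805, 2896, 12236, 13734, 21922 and, for all stages, 40072. Where both compared stages kept all their libraries, leaving out other libraries or stages did not change their means. Those counts, such as 7014 and 8813 for 16 h against 3 h, moved through the estimate of spread that the stages share. Apart from these, and from fewer genes or no fold limit by construction, the cause was not tested. Leaving out 1 replicate gave 3 to 9223, 11 to 833, 1231 to 2604, 1018 to 1421, 2207 to 3054, 5604 to 6593, 2712 to 7407, 13065 to 15048 and 15854 to 24854, where 9223, 7407 and 24854 come without early desiccation replicate 3. The 27 h against dry seed count stayed within 1.5 times except for abundant genes alone. The pseudocount of 5, no filter and run 1 alone left all counts within 1.5 times. The correlation of desiccation and imbibition changes was 0.0254. Its range over library choices comes from the same libraries, so lying inside that range is no check. From mid against early desiccation and 27 h against 3 h the correlation was -0.0769 (Spearman rho = -0.130), for which no such range was made. Without both doubted libraries the correlation of 0.0254 became 0.112.

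The replicate number as a block gave 30, 259, 1790, 1541, 3207, 6709, 3455, 14675 and 16958 genes, and changed no count by 1.5 times. The block is no check of the correlation of desiccation and imbibition changes (0.0254). Each stage holds the same replicate numbers, so a block cannot alter differences of stage means. The numbers did not pair the samples: of 63 pairs with the same number 25 had deviations correlated above 0.1, with a range from -0.74 to 0.70, and 8 of 21 replicates correlated best with their own number. Of the 30 changes of named genes, none reversed. For most settings the naming rule fixed this outcome, since replicates that do not overlap keep the sign of a change. DESeq2 gave no adjusted p for 6 of the 30 changes. The calls lost numbered 2 with edgeR, 5 with only the compared stages, 1 with run 1 alone and 19 over all fits that left out 1 replicate. Gene list tests were not run, because the reference used here matched none of the IDs and gives no products. Depth limits late desiccation replicate 3 most, where 1 read is worth 8.68 normalized counts.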

Other observations

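All tests in this part were chosen after the results they bear on were seen. Several lists of called genes overlapped later lists more than independent lists would, in both directions, in comparisons that share no library. Of the 972 genes that rose from dry seed to 3 h, 292 (30%) fell from 16 h to 27 h, against 81.2 expected for independent lists, and 63 rose, against 62.7 expected. Among genes with a mean of at least 200, 187 of 489 fell, against 115.6 expected. Of the 238 genes that fell from mid to late desiccation, 47 (19.7%) rose from dry seed to 3 h, against 5.0 expected, and 34 of 174 abundant ones did so, against 7.1. Genes that rose from late desiccation to dry seed fell from 3 h to 16 h in 75 of 693 cases, against 15.7 expected, and in 55 of 409 abundant ones, against 27.2. Some moves in the same direction were in excess too. Of the 611 genes that fell from dry seed to 3 h, 122 fell again from 16 h to 27 h, against 51 expected, and 106 rose, against 39.4; of 349 abundant ones 92 fell, against 82.5, and 51 rose, against 25. Of the falls from mid to late desiccation, 71 fell again from 16 h to 27 h, against 19.9 expected, and 39 rose, against 15.4; of 174 abundant ones 61 fell, against 41.1, and 27 rose, against 12.5. Of the 1186 falls from late desiccation to dry seed, 242 fell again in that step, against 99.1 expected, and 106 rose, against 76.5; of 410 abundant ones 149 fell, against 96.9, and 22 rose, against 29.4. Genes are not independent, so these counts carry no p-value. The lists also share each gene's spread, estimated from all 21 replicates, so genes of low spread are called more readily in every comparison. Expected values also divide by all genes tested, including low genes, which were called less often. How much of the excess comes from either was not tested.

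A pair of very abundant genes swung between replicates of one stage. Glyma11g33922 ranged from 44.7 to 4855 normalized counts in early desiccation and Glyma09g28800 from 101.3 to 8059. Over 21 replicates of all stages their log2 values correlated at 0.991. Large stage differences that both genes share enter this value, so it does not show that they vary together within a stage.

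Among genes with a mean of at least 10 in the other stages, 14 that follow each other in ID order on chromosome 13 had 0 reads in dry seed, and no other stage had a run longer than 2. The run of 2, at 27 h, was Glyma13g12210 and Glyma13g12220, shortly after the 14 genes. With all IDs kept, the region of the 14 genes holds 765 IDs (Glyma13g01791 to Glyma13g12191), of which 416 had reads in other stages and 5 had dry-seed reads, 9 in all. Its longest unbroken run in dry seed was 310 IDs, against 40 to 67 in the other stages, which also lie in this region. Low depth is argued against: at the lowest mean of any other stage, 8498 reads would be expected. A loss of single transcripts one by one is argued against as well, because the 30 such genes with 0 reads in dry seed, shuffled over 37780 genes 1000 times, formed runs of at most 2. A stretch missing from the mapping or counting of the dry-seed libraries, or from the genome of that seed lot, remains a candidate explanation; these cannot be told apart, since both leave 0 reads for the 14 genes in all 3 replicates, as seen. Low dry-seed values went on past the run. Glyma13g12201 had a mean of 0.401 normalized counts in dry seed against 3219 in the other stages. Glyma13g12210 and Glyma13g12220 had 0 against 53.8 and 11.6, while the next such gene, Glyma13g12280, had 16.1 against 23.0. Changes at dry seed of genes in this run, and of these neighbours with low values, may therefore not reflect transcript levels. Of the 972 rises at 3 h, 14 lie in the run itself.

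The background of quiet genes differed between replicates of one stage by a factor of 46.5 in early desiccation, 7.56 in late desiccation and 6.71 in dry seed (lowest of the high replicates over highest of the low). Sequencing depth is argued against, since in run 1 alone the smallest of these factors was 6.40, with depths that differed by less than 2-fold within stages: 6.40 to 11.95 M reads in early desiccation, 2.53 to 3.26 M in late desiccation and 14.37 to 17.24 M in dry seed. Early desiccation replicate 3, with the highest background, had the lowest run 1 depth of its stage. The excess had a similar profile over genes in the 3 stages, on libraries that do not overlap (Spearman 0.576, 0.545 and 0.435 across 8959 genes). Since the low replicates held little, the excess lies close to each gene's level in the high replicates. Such levels can correlate between stages for other reasons, so this does not decide whether 1 shared background was added in different amounts. The source of the excess, such as genomic DNA or other RNA, was not tested. No biological explanation was tested, as the replicates share a stage.

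Early desiccation replicate 3 stood apart from replicates 1 and 2 also in very abundant genes. A swap with late desiccation replicate 3 is argued against: that library correlated better with late desiccation replicates 1 and 2 than with early desiccation replicates 1 and 2 over 1210 genes, by 0.425 with gene means removed and 0.183 with gene means kept. Added background at the level of the quiet genes is argued against as the whole cause. Scaling can lower all abundant genes alike, and the median log2 difference from replicates 1 and 2 was -0.35 (normalized totals 16.11 M against 20.35 M and 21.61 M). After this median was removed, 10.3% of the genes still lay at least 2-fold lower (19.8% before), against at most 4% in the other 20 replicates set against their stage. A library of another stage under the wrong label stays open. With gene means removed it correlated with each other stage less well than the least similar library of that stage did, mid desiccation being closest at a difference of -0.153. With gene means kept the difference was -0.027 for mid desiccation and -0.037 for 3 h, too small to decide. A mixture of early desiccation seeds with seeds of 1 other stage stays open as well. Of the 1210 genes, 15.4% lay at least 2-fold off replicates 1 and 2 in either direction after the median was removed, and 2.6% off the best mixture with 3 h, while the other 20 replicates lay up to 7.4% off their own stage. Mid desiccation and 3 h alone gave 5.7% and 4.2%, so a mixture and a wrong label cannot be told apart by this share. The best mixture with 3 h held 92% 3 h and that with mid desiccation 100% mid desiccation, so little or no early desiccation. With 16 h it held 64% 16 h, and 5.3% of the genes lay off it. On the way from early desiccation to 3 h the library had a median position of 0.61 for genes higher there and 0.81 for genes lower there (quartiles 0.34 to 0.84 and 0.69 to 0.91). Towards mid desiccation they were 0.84 and 1.31 (quartiles 0.52 to 1.43 and 1.09 to 1.37). Towards late desiccation these positions were 0.13 and 0.79, with quartiles that did not overlap (0.03 to 0.53 and 0.55 to 0.92), unlike a simple mixture with that stage. A sample of an age between the stages was not tested.

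All 10 splits of the 6 replicates in each comparison were counted, the real one included, which are too few for a share under 0.05. As many genes as the real split were given by 1 of 10 splits, the real one itself, for late against mid desiccation (292 genes, highest other 2), 3 h against dry seed (1583, highest other 0), 16 h against 3 h (3275, highest other 0), 27 h against 16 h (6890, highest other 0) and 27 h against dry seed (14992, highest other 0). For mid against early desiccation 3 of 10 splits, real one included, gave as many (23, highest other 1058), for dry seed against late desiccation 2 (1879, highest other 4530) and for dry seed against early desiccation 2 (3541, highest other 18378). In the first of these 3 the leading split set early desiccation replicates 1 and 2 with mid desiccation replicate 1. In the next it set late desiccation replicates 1 and 2 with dry seed replicate 2, and in the last early desiccation replicates 1 and 2 with dry seed replicate 1. The latter 2 follow the order of the quiet-gene means. The first does not, as mid desiccation replicate 2 had a lower mean than replicate 1 (3.46 against 4.54). Whether the background gives these splits was not tested. Across the 7 stages 2 of 100 splits gave as many genes (17459, highest other 18683), a share under 0.05, real grouping included, though 1 drawn regrouping gave more genes than the stages.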
